A study of Homo sapiens with 302 samples.

How the data were processed

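Total RNA of 302 lymph node biopsies, titled as untreated follicular lymphoma, was measured by the authors on expression arrays, and all 302 form 1 group. The text on the design of the series speaks of sorted cell populations from such nodes, while the sample labels speak of biopsies; the sample labels were followed, and this difference stays open. Per the labels, RNA was extracted with TRIzol and RNeasy Midi columns, checked by spectrophotometer and Bioanalyzer, and labelled with biotin. The deposited values are intensity on a linear scale, 1 per probe set and array, and the labels name MAS5 and the affy package without versions. The 2% trimmed mean of the intensities was 500.0 in every array, so the authors scaled each array to a common level. The median intensity of an array ran from 65.93 to 182.42. Arrays have no read depth, and their number limits the precision of the values. No values were missing.

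Of 54675 probe sets, 11777 had no gene listed and 1801 listed several genes. These were left out, as were 62 control probe sets. The remaining probe sets gave 19775 genes, each taken from its brightest probe set. From these, 45 genes of XIST and the Y chromosome were left out of the tests, which left 19730. Values were log2 of intensity plus 16. The 9865 genes whose mean over the biopsies was at or above the median of all gene means (7.80) were tested. The gene lists hold 500 distinct genes in 41 lists: 6 main scores, 18 further cell types, 15 functions, genes of follicular lymphoma and light chain genes; 452 were measured, and the other 48 were not analysed here. A score is the mean over a list's measured genes of the z value over biopsies.

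The questions were how cell type scores vary together, which genes move with each score, and which genes have 2 levels or a large spread. Correlations are Pearson r and Spearman rho with two-sided permutation tests of 100000 resamples, Benjamini-Hochberg adjusted within each family, and r was given again without the 2 biopsies farthest from the median of the first score. The labels give no batch, so 8 blocks of title order served as possible batches. The joint model used limma with the 6 main scores as terms, each list member against scores made without it, and genes were called at an adjusted p under 0.05 and a slope of at least 0.25 log2 units per SD. Counts of genes called are given as a percent of the 9865 tested genes, also where an alternative tested more or fewer genes. Genes with 2 modes came from mixtures of normal distributions, called at a gain in BIC over 10, a smaller share of at least 10% and modes 3 component SDs apart. The closeness of a list was set against 10000 random lists matched on level in 20 bins. Named genes are list members, the 12 steepest higher and 6 steepest lower called genes per term that are in no list and whose plain correlation has the same sign, the 20 genes of largest SD and the 12 genes with 2 modes of largest gain. On simulated data the joint model called 87.0% of genes with a slope of 0.3. For 9305 genes with none it made 1 call, 0.002% of their tests on the 6 scores. These genes were shuffled singly, which ends their correlation with each other. Fits of the real genes to shuffled scores, which keep it, called up to 4.16% of genes for a score. The mixture called 1.3% of simulated genes with modes 2.5 SDs apart and all with modes 3.5 or 5 apart.

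The gene lists, tests, thresholds, the naming rule and the alternatives of other pseudocounts (1 and 64), quantile normalization, the mean of probe sets, median scores, adjustment for array measures or blocks, leaving out 25 doubtful arrays, other filters and partial correlations were chosen before the data were examined. Chosen after the data were seen were the alternatives of adjusting for control probe sets, of all technical measures together, of scores from genes above the median level, of leaving out the 26 biopsies of the lower stromal mode and of a skewed distribution, and the rule that relations of lists in separate clusters are given within each. The random lists and genes of like level set against the correlations were chosen then too. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.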

Results

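The samples were 302 lymph node biopsies of untreated follicular lymphoma, a slow-growing cancer of germinal centre B cells, and they formed 1 group. Total RNA of each biopsy was measured on 1 expression array, and each array gave an intensity for 54675 probe sets. The median intensity of an array ran from 65.93 to 182.42, with a median of 101.75 over the 302 arrays, and the number of arrays limits the precision of every value. Arrays have no read depth. The study used these arrays to evaluate a method that estimates cell types from mixed tissue, so the comparisons ask how the transcripts of the cell types of a lymph node varied together. The labels do not say whether each biopsy came from a separate patient. The p-values treat the biopsies as independent, which could not be checked, and may be too small if a patient gave more than 1.

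B cell and macrophage transcripts varied in opposite directions across the biopsies. The B cell score was the mean of 15 genes such as MS4A1 (CD20), CD79B (a signalling chain of the B cell receptor) and PAX5 (the transcription factor that keeps B cell identity). It was low where the macrophage score was high (r -0.63, rho -0.67, trimmed r -0.65, blocks -0.74 to -0.44). Trimmed r leaves out the 2 biopsies farthest from the median of the first score. Blocks gives the lowest and highest r within 8 blocks of 37 to 38 biopsies in the order of the title numbers. Permutation p-values, raw and adjusted, are given for r and then rho. The macrophage score held 14 genes, among them CD14, the scavenger receptor CD163 and the complement genes C1QA, C1QB and C1QC. The T cell score, with genes of the CD3 complex, CD2, CD28 and LCK, and the cytotoxic score, with CD8A, granzymes and perforin (PRF1), varied together (r 0.76, rho 0.79, trimmed r 0.78, blocks 0.54 to 0.85). Macrophage transcripts went with cytotoxic transcripts (r 0.35, rho 0.42, trimmed r 0.36, blocks -0.02 to 0.73) and, less closely, with T cell transcripts (r 0.26, rho 0.33, trimmed r 0.23, blocks -0.14 to 0.62, p 2e-05 and 1e-05, adjusted 5e-05 and 1.87e-05). B cell transcripts were lower where T cell (r -0.22, rho -0.36, trimmed r -0.28, blocks -0.71 to 0.07, p 0.0002 and 1e-05, adjusted 0.000375 and 1.87e-05) and cytotoxic transcripts (r -0.24, rho -0.34, trimmed r -0.29, blocks -0.74 to 0.00, p 3e-05 and 1e-05, adjusted 6.43e-05 and 1.87e-05) were higher. The cell cycle score, with MKI67, TOP2A and the mitotic cyclins, went weakly against the cytotoxic score (r -0.17, rho -0.17, trimmed r -0.15, blocks -0.43 to 0.08, p 0.00346 and 0.00287, adjusted 0.00577 and 0.00478). It had no relation that passed with the B cell score (r 0.11, rho 0.07, trimmed r 0.05, blocks -0.28 to 0.51, p 0.0565 and 0.257, adjusted 0.0848 and 0.322). That r did pass with median scores, the mean of probe sets, adjustment for control probe sets, or without the 26 biopsies of the lower stromal mode. With the macrophage score (r -0.08, rho -0.14, trimmed r -0.13, blocks -0.23 to 0.22, p 0.169 and 0.0132, adjusted 0.23 and 0.0181) and the T cell score (r -0.02, rho -0.16, trimmed r -0.15, blocks -0.43 to 0.49, p 0.785 and 0.00579, adjusted 0.841 and 0.00868) the relation of the cell cycle score passed by rho and not by r. By r, 9 of the 15 pairs of the 6 main scores passed at an adjusted p under 0.05, and the same 9 passed by rho too. Of these 4 were positive and 5 negative, and all 9 kept their sign in at least 6 of the 8 blocks. Where no p is given, both raw p-values were 1e-05, the smallest that 100000 resamples can give, which is 3e-05 for r and 1.87e-05 for rho after adjustment over the 15 pairs. Random gene lists of like size and level gave a median r of -0.07 and a lowest 2.5% limit of -0.38 for the B cell and macrophage pair. The relations of macrophages with T cells and with cytotoxic cells and that of cytotoxic cells with the cell cycle lay inside the middle 95% of such random lists, at the 83.85th, 86.65th and 5.88th percentile. With the other main scores held fixed, the B cell and T cell relation ended (partial r = -0.01, adjusted p = 0.829) and that of T cells and macrophages turned negative (partial r = -0.16). The relation of cytotoxic cells with the cell cycle no longer passed then either, and that of T cells with the cell cycle turned positive.

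By the rule for separate clusters the stromal score had 2 modes, a call that ended after adjusting for RNA quality and brightness of the arrays. The stromal score, the mean z value of 14 genes of fibroblasts and their matrix such as COL1A1, COL3A1, FN1 and LUM, had 1 mode at -2.35 with 26 biopsies and another at 0.22 with the other 91.4%, called the upper-mode biopsies here. The modes lay 4.90 component SDs apart, and the gain in BIC was 137.6 over 1 normal and 77.7 over 1 skewed distribution. No empty gap divided the modes, with 1 biopsy at scores of -1.5 to -1.25 and 3 at -1.25 to -1.0. The fibroblastic reticular list, with the homing chemokines CCL19, CCL21 and CXCL12, and the endothelial list, with VWF and CDH5, had 2 modes by the same rule, with gains of 158.8 and 79.3 over 1 normal distribution. Relations of these 3 lists are therefore given within the upper-mode biopsies. There the stromal score was lower where B cell transcripts were higher (r -0.47, rho -0.41, trimmed r -0.44, blocks -0.80 to -0.15) and higher where macrophage transcripts were higher (r 0.48, rho 0.47, trimmed r 0.50, blocks 0.20 to 0.67). No relation passed with T cells (r 0.00, rho 0.02, trimmed r -0.03, blocks -0.08 to 0.14, p 0.977 and 0.717, adjusted 0.977 and 0.828), with cytotoxic cells (r -0.04, rho 0.00, trimmed r 0.01, blocks -0.29 to 0.17, p 0.538 and 0.938, adjusted 0.672 and 0.938) or with the cell cycle (r -0.03, rho -0.02, trimmed r -0.04, blocks -0.23 to 0.24, p 0.653 and 0.777, adjusted 0.754 and 0.833). After adjusting for the array measures all 3 passed, at -0.16, -0.18 and 0.17, and with all technical measures at -0.14, -0.18 and 0.21, in the opposite direction for T cells and for the cell cycle. Within the 26 other biopsies the stromal score went with the cell cycle score (r 0.66, rho 0.65, trimmed r 0.67, p 0.00013 and 0.00041, adjusted 0.00065 and 0.00205), while the remaining 4 main pairs with stroma did not pass there, though that with cytotoxic cells did with the other main scores held fixed (-0.57). This relation no longer passed after adjusting for the array measures (0.40), the poly-A controls (0.43) or all technical measures (0.25). That of stroma with macrophages passed under each of these, at 0.61, 0.58 and 0.73. Lists were called at a smaller share of at least 5%, and adjusting for RNA quality and brightness of the arrays ended the call, with a gain in BIC of 17.4 and 95.6% of biopsies upper. Adding control spikes and blocks left a gain of -5.8. With the other main scores held fixed, the cytotoxic relation to stroma passed at -0.43. The rule for separate clusters was set after the data had been seen.

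**Figure D1:**
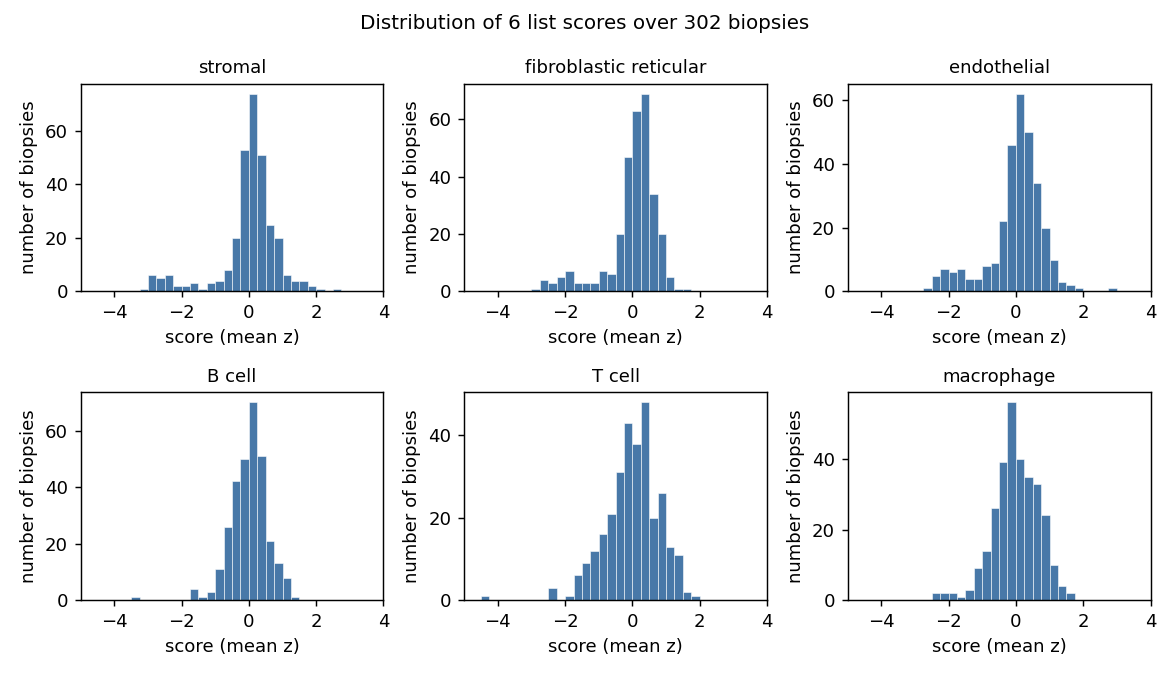
Number of biopsies (vertical axis) by list score in mean z units (horizontal axis, bins of 0.25) for 6 lists over all 302 biopsies. The stromal, fibroblastic reticular and endothelial scores have a second mode at low values by the rule used, and the B cell, T cell and macrophage scores do not. For the stromal score it holds 26 biopsies with a mode at -2.35, and no empty gap divides it from the rest.

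Each other cell type was followed by its own list against the 6 main scores. Germinal centre B cell transcripts, such as MME and S1PR2, went with the cell cycle score (r 0.51, rho 0.43, trimmed r 0.47, blocks 0.34 to 0.67). They also went with the B cell score (r 0.35, rho 0.27, trimmed r 0.29, blocks 0.09 to 0.46) and against the cytotoxic score (r -0.35, rho -0.35, trimmed r -0.33, blocks -0.54 to -0.13). Transcripts of naive and memory B cells went with the B cell score (r 0.45, rho 0.35, trimmed r 0.38, blocks 0.14 to 0.72). Within the upper-mode biopsies they went against stroma (r -0.42, rho -0.32, trimmed r -0.39, blocks -0.61 to -0.18). Plasma cell transcripts went with cytotoxic cells (r 0.26, rho 0.29, trimmed r 0.24, blocks 0.09 to 0.53, p 2e-05 and 1e-05, adjusted 4.32e-05 and 2.08e-05). Among T cells, follicular helper (r 0.73, rho 0.68, trimmed r 0.69, blocks 0.59 to 0.84), naive and central memory (r 0.66, rho 0.64, trimmed r 0.67, blocks 0.55 to 0.83) and regulatory transcripts (r 0.63, rho 0.59, trimmed r 0.58, blocks 0.37 to 0.80) each went with the T cell score. The regulatory list also went with macrophages (r 0.38, rho 0.40, trimmed r 0.39, blocks 0.18 to 0.58) and against B cells (r -0.35, rho -0.47, trimmed r -0.44, blocks -0.65 to 0.14). The follicular helper list also went with the cell cycle (r 0.30, rho 0.15, trimmed r 0.17, blocks -0.15 to 0.70, p 1e-05 and 0.00724, adjusted 2.4e-05 and 0.0103). NK cell transcripts went with the cytotoxic score (r 0.50, rho 0.49, trimmed r 0.49, blocks 0.29 to 0.63) and against the cell cycle (r -0.39, rho -0.30, trimmed r -0.32, blocks -0.56 to -0.02). Conventional dendritic cell transcripts went with T cells (r 0.50, rho 0.43, trimmed r 0.45, blocks 0.35 to 0.74). Those of plasmacytoid dendritic cells went with macrophages (r 0.45, rho 0.44, trimmed r 0.45, blocks 0.16 to 0.65). The naive and memory B list and the plasmacytoid dendritic list are loose sets, at the 86.6th and 75.6th percentile of random lists in how closely their tested genes vary together, and at the 92.8th and 99.5th over all measured genes. Of the NK cell genes 2 of 9 reached the level of the tested genes, so this score rests mostly on weak signals and could not be made from tested genes alone. Over its 9 genes the mean pairwise r was 0.104, against a random median of 0.028. Random lists of like size and level in place of a list often reached such values. Inside their middle 95% lay germinal centre B transcripts with the cell cycle (95.46th percentile) and B cells (80.3rd), plasma cells with cytotoxic cells (87.55th) and follicular helper transcripts with the cell cycle (75.93rd). So did regulatory T transcripts with macrophages (87.31st) and B cells (12.8th) and plasmacytoid dendritic ones with macrophages (92.98th), while the other relations of these lists named above lay outside.

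Among the lists of the tissue framework, fibroblastic reticular transcripts went with macrophages (r 0.62, rho 0.63, trimmed r 0.63, blocks 0.40 to 0.77), with stroma (r 0.54, rho 0.51, trimmed r 0.55, blocks 0.25 to 0.72) and against B cells (r -0.52, rho -0.50, trimmed r -0.52, blocks -0.76 to -0.22) within the upper-mode biopsies. Endothelial transcripts did likewise with stroma (r 0.53, rho 0.46, trimmed r 0.54, blocks 0.35 to 0.66), macrophages (r 0.48, rho 0.50, trimmed r 0.48, blocks 0.29 to 0.56) and B cells (r -0.46, rho -0.38, trimmed r -0.40, blocks -0.82 to -0.15). Follicular dendritic transcripts, with the complement receptor CR2 and FDCSP, went with macrophages (r 0.53, rho 0.43, trimmed r 0.49, blocks 0.19 to 0.68) and against B cells (r -0.38, rho -0.43, trimmed r -0.42, blocks -0.54 to -0.11) over all 302. Within the 26 biopsies of the lower stromal mode 8 of the 28 pairs of cell lists passed by r and 3 of them by rho too. These 3 were stroma with fibroblastic reticular (r 0.84, rho 0.82, trimmed r 0.79, p 1e-05 and 1e-05, adjusted 0.00014 and 0.00028), follicular dendritic (r 0.78, rho 0.71, trimmed r 0.69, p 1e-05 and 0.00012, adjusted 0.00014 and 0.00168) and NK cell transcripts (r -0.51, rho -0.58, trimmed r -0.53, p 0.00793 and 0.00263, adjusted 0.037 and 0.0245). Within the upper-mode biopsies stroma with follicular dendritic transcripts passed by rho only (r 0.10, rho 0.16, trimmed r 0.12, blocks -0.17 to 0.31, p 0.11 and 0.00739, adjusted 0.147 and 0.0104) and with NK cells by neither (r -0.05, rho 0.01, trimmed r 0.00, blocks -0.19 to 0.11, p 0.417 and 0.835, adjusted 0.479 and 0.859). After adjusting for the array measures both passed there, at 0.23 and -0.21. Within the 26 biopsies fibroblastic reticular transcripts went with the cell cycle (r 0.53, rho 0.46, trimmed r 0.36, p 0.0048 and 0.0177, adjusted 0.0293 and 0.0937) and against it in the upper mode (r -0.30, rho -0.32, trimmed r -0.26, blocks -0.44 to -0.04). This relation and that of NK cells within the 26 ended after adjusting for the array measures (0.33 and -0.32) or the blocks and with the mean of probe sets. They were -0.14 and -0.11 with the other main scores held fixed. The relation of B cells with follicular dendritic transcripts was 0.07 once the other main scores were held fixed, and that of macrophages and regulatory T cells was -0.03. Relations of macrophages with follicular dendritic transcripts (0.10), of B cells with endothelial (-0.14) and regulatory T transcripts (-0.10) and of stroma with naive and memory B transcripts (-0.13) no longer passed then. Transcripts of neutrophils and blood monocytes went with cytotoxic cells (r 0.41, rho 0.47, trimmed r 0.41, blocks 0.25 to 0.59). Those of mast cells went with macrophages (r 0.37, rho 0.34, trimmed r 0.37, blocks -0.22 to 0.59). Transcripts of the adipocyte list went with macrophages (r 0.42, rho 0.42, trimmed r 0.42, blocks 0.21 to 0.54) and against B cells (r -0.47, rho -0.39, trimmed r -0.40, blocks -0.73 to -0.27). They could come from fat around the node, but the cells that made them were not tested. Erythroid transcripts, a sign of blood, went weakly against stroma within the upper-mode biopsies (r -0.20, rho -0.16, trimmed r -0.22, blocks -0.50 to 0.25, p 0.00088 and 0.00608, adjusted 0.00153 and 0.00912). Epithelial ones went weakly with macrophages (r 0.17, rho 0.17, trimmed r 0.17, blocks -0.08 to 0.57, p 0.00263 and 0.00398, adjusted 0.00437 and 0.00632), which was -0.02 with the other scores held fixed. For the muscle list no relation passed by r, and that with the cell cycle passed by rho (r -0.08, rho -0.16, trimmed r -0.07, blocks -0.51 to 0.15, p 0.147 and 0.00598, adjusted 0.187 and 0.0091). Of the mast cell genes 1 of 7 reached the level of the tested genes, as did 1 of 6 erythroid, 0 of 9 muscle, 3 of 11 epithelial and 3 of 10 adipocyte genes, so these scores rest mostly on weak signals. Inside the middle 95% of random lists lay endothelial transcripts with macrophages (95.92nd percentile) and B cells (5.67th) and fibroblastic reticular ones with the cell cycle (3.23rd). The relations of macrophages with mast cell (88.47th), adipocyte (95.96th) and epithelial transcripts (69.42nd) did so too, as did that of muscle with the cell cycle (92.67th). Of the pairs of these 18 lists with the 6 scores, 74 passed by r, 49 positive and 25 negative. Of these 69 passed by both coefficients, and 70 kept their sign in at least 6 blocks, while 25 of the 74 lay outside the middle 95% of random lists. Unlisted p-values here are 1e-05 before and 2.4e-05 for r and 2.08e-05 for rho after adjustment.

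**Figure D2:**
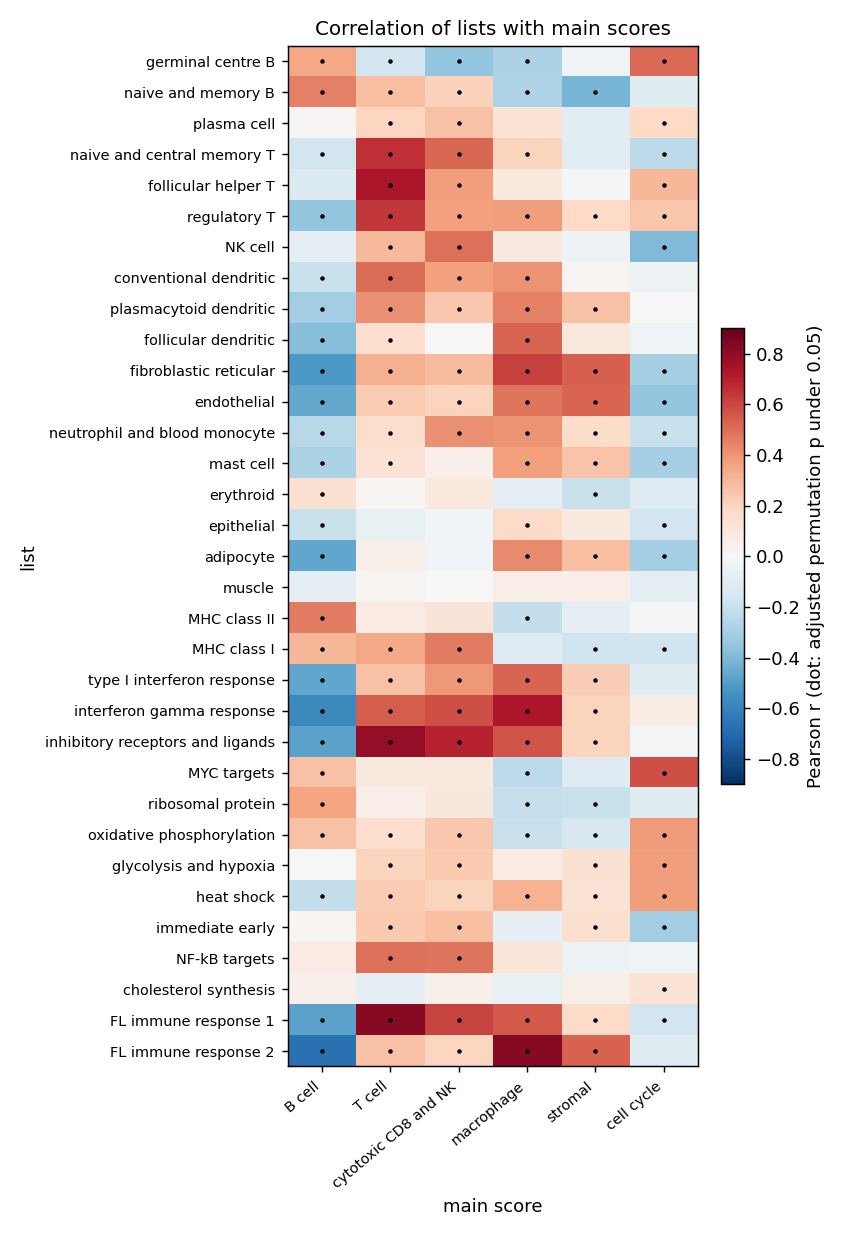
Pearson correlation r, in colour from -0.9 to 0.9, of each list (vertical axis) with the 6 main scores (horizontal axis), with a dot where the adjusted permutation p is under 0.05. Relations with the stromal score and of the fibroblastic reticular and endothelial lists are over 91.4% of biopsies and all others over 302, and the interferon gamma list reaches 0.73 with macrophages and -0.58 with B cells.

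Interferon-induced genes followed macrophages and cytotoxic cells. The interferon gamma list held the T cell attracting chemokines CXCL9 and CXCL10 and the guanylate-binding proteins GBP1 and GBP5. It went with macrophages (r 0.73, rho 0.74, trimmed r 0.73, blocks 0.59 to 0.81) and cytotoxic cells (r 0.58, rho 0.63, trimmed r 0.58, blocks 0.33 to 0.90) and against B cells (r -0.58, rho -0.65, trimmed r -0.63, blocks -0.75 to -0.20). The type I interferon list, such as MX1 and IFIT3, also went with macrophages (r 0.52, rho 0.58, trimmed r 0.55, blocks 0.27 to 0.73), which did not pass with the other main scores held fixed (0.11). Inhibitory receptors and ligands, such as TIGIT, CTLA4 and LAG3, varied with T cells (r 0.79, rho 0.79, trimmed r 0.78, blocks 0.68 to 0.91) and cytotoxic cells (r 0.70, rho 0.73, trimmed r 0.71, blocks 0.55 to 0.82). TIGIT is also in the follicular helper list and CTLA4 in the regulatory T list, so the relation to T cells follows in part from the members. MHC class II genes followed B cells (r 0.46, rho 0.33, trimmed r 0.42, blocks 0.06 to 0.62). MHC class I genes followed cytotoxic cells (r 0.47, rho 0.42, trimmed r 0.46, blocks 0.26 to 0.64), T cells (r 0.35, rho 0.39, trimmed r 0.43, blocks 0.05 to 0.64) and B cells (r 0.30, rho 0.22, trimmed r 0.30, blocks -0.15 to 0.56, p 1e-05 and 7e-05, adjusted 2.73e-05 and 0.000157). The NF-kB target list went with T cells (r 0.50, rho 0.51, trimmed r 0.52, blocks 0.04 to 0.70). The published prognostic gene sets of follicular lymphoma lined up with cell types. Immune response 1 holds T cell genes such as CD7, LEF1 and IL7R, the last 2 also in the naive and central memory T list. Its relation to T cells therefore follows in part from its members. Immune response 1 went with T cells (r 0.82, rho 0.81, trimmed r 0.81, blocks 0.72 to 0.93), and immune response 2 with macrophages (r 0.82, rho 0.82, trimmed r 0.82, blocks 0.75 to 0.87) and against B cells (r -0.67, rho -0.71, trimmed r -0.69, blocks -0.90 to -0.51). The type I interferon list with macrophages (96.58th percentile) and MHC class II (91.88th) and class I (67.27th) with B cells lay inside the middle 95% of random lists, and the other relations named with them outside.

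MYC targets followed the cell cycle score more closely than 97.5% of random lists, and other growth and metabolism lists did not. MYC targets, such as NME1 and LDHA, had the closest relation to it among the function lists (r 0.58, rho 0.61, trimmed r 0.60, blocks 0.24 to 0.70). Oxidative phosphorylation (r 0.38, rho 0.48, trimmed r 0.45, blocks 0.10 to 0.59), glycolysis and hypoxia (r 0.38, rho 0.37, trimmed r 0.40, blocks 0.09 to 0.69) and heat shock genes (r 0.37, rho 0.32, trimmed r 0.30, blocks -0.01 to 0.66) went with it too. Cholesterol synthesis did so at the margin (r 0.12, rho 0.19, trimmed r 0.20, blocks -0.28 to 0.39, p 0.0336 and 0.00079, adjusted 0.0489 and 0.00139), and that call ended with median scores, with the mean of probe sets and without doubtful arrays. Random lists in place of oxidative phosphorylation had a median r of 0.278 with the cell cycle and a 97.5% limit of 0.54, which puts its value at the 75.71st percentile. Glycolysis and hypoxia lay at the 83.38th, heat shock at the 83.17th and cholesterol synthesis at the 60.33rd percentile of such lists. Immediate early genes such as FOS, JUN and DUSP1, which respond to handling of tissue, went against it (r -0.31, rho -0.26, trimmed r -0.27, blocks -0.52 to -0.04). Ribosomal protein genes went with B cells (r 0.36, rho 0.35, trimmed r 0.37, blocks 0.09 to 0.58), at the 70.03rd percentile of random lists. Of the 90 pairs of function lists, 62 passed by r, 46 positive and 16 negative. Of these 60 passed by both coefficients and 59 kept their sign in at least 6 blocks, 23 of the 62 lay outside the middle 95% of random lists, and unlisted p-values are 1e-05 before and 2.73e-05 for r and 2.43e-05 for rho after adjustment. With the other main scores held fixed, 39 pairs passed, and within the 26 biopsies 6 of 15 function lists passed with stroma by r and 0 by rho too.

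Of the genes mutated in follicular lymphoma, IRF8 and HVCN1 tracked B cells and EZH2 tracked division more closely than 97.5% of random genes of like level. IRF8, a transcription factor of germinal centre B cells (r 0.55, rho 0.45, trimmed r 0.51, blocks 0.18 to 0.70), and the proton channel gene HVCN1 (r 0.53, rho 0.52, trimmed r 0.52, blocks 0.25 to 0.70) were higher where B cell transcripts were higher. So were the acetyltransferase gene CREBBP (r 0.44, rho 0.46, trimmed r 0.43, blocks 0.16 to 0.65), STAT6 (r 0.44, rho 0.39, trimmed r 0.43, blocks 0.25 to 0.69) and BCL6 (r 0.44, rho 0.47, trimmed r 0.43, blocks 0.16 to 0.60). EZH2, the histone H3 lysine 27 methyltransferase, followed the cell cycle (r 0.64, rho 0.65, trimmed r 0.68, blocks 0.51 to 0.79), as did the migration receptor gene S1PR2 (r 0.45, rho 0.40, trimmed r 0.39, blocks 0.19 to 0.63). TNFRSF14, which encodes the receptor HVEM, followed T cells (r 0.43, rho 0.56, trimmed r 0.55, blocks -0.07 to 0.82) and went against the cell cycle (r -0.40, rho -0.36, trimmed r -0.34, blocks -0.56 to 0.10). PRDM1, the plasma cell regulator, and TNFAIP3, an inhibitor of NF-kB signalling, also followed T cells (r 0.39, rho 0.40, trimmed r 0.37, blocks -0.18 to 0.77, and r 0.36, rho 0.37, trimmed r 0.37, blocks 0.01 to 0.61). Among random genes CREBBP (95.48th percentile), STAT6 (94.57th) and BCL6 (92.9th) with B cells and S1PR2 with the cell cycle (95.19th) lay inside the middle 95%. So did TNFRSF14 (96.86th), PRDM1 (96.41st) and TNFAIP3 (97.02nd) with T cells, while TNFRSF14 with the cell cycle lay outside (0.4th). Of the 96 pairs of 32 genes with the B cell, T cell and cell cycle scores, 61 passed by r, 39 positive and 22 negative. Of these 55 passed by both coefficients, 57 kept their sign in at least 6 blocks, and 7 of the 61 lay outside the middle 95% of random genes. By definition that range leaves some random genes outside for each pair. With 96 pairs examined, random genes would reach some of these 7 places too, and the genes singled out above are the extremes of the set. Unlisted p-values are 1e-05 before and 3.56e-05 for r and 2.59e-05 for rho after adjustment.

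BCL2, the survival gene that the t(14;18) translocation of this lymphoma activates, had 2 modes, at log2 values of 10.39 and 12.78, and is therefore described within each. In the lower mode, with all but 130 of the biopsies, BCL2 was higher where T cell transcripts were higher (r 0.49, rho 0.44, trimmed r 0.39, p 1e-05 and 1e-05, adjusted 6e-05 and 3e-05). It was lower where B cell transcripts were higher (r -0.36, rho -0.44, trimmed r -0.38, p 2e-05 and 1e-05, adjusted 6e-05 and 3e-05). In the 130 biopsies of the upper mode the signs were the opposite, with r = -0.22 for T cells (rho -0.24, trimmed r -0.22, p 0.0138 and 0.00557, adjusted 0.0207 and 0.00668). For B cells r was 0.29 (rho 0.33, trimmed r 0.31, p 0.00075 and 0.0002, adjusted 0.0015 and 0.0004). With the cell cycle score no relation passed by r in the lower mode (r 0.0049, p 0.949, adjusted 0.949), where rho was -0.23 (p 0.00297, adjusted 0.00445) and r without 2 biopsies -0.26, so that r rests on those 2. In the upper mode neither coefficient passed (r -0.12, rho -0.12, trimmed r -0.14, p 0.172 and 0.155, adjusted 0.207 and 0.155). Within the blocks the T cell relation of the lower mode ran from 0.28 to 0.79 and the B cell relation from -0.68 to -0.06. In the upper mode the block values ran from -0.58 to 0.15 for T cells, negative in 6 of 8, and from 0.03 to 0.68 for B cells. These 6 relations were adjusted together. With the other main scores held fixed, the T cell relation of the lower mode was 0.45 and passed, while the B cell relation of that mode (-0.08) and those of B cells (0.14) and T cells (-0.07) in the upper mode did not. The T cell relation of the upper mode also ended with the mean of probe sets (-0.05) and after adjusting for the array measures (-0.16). With the mean of its probe sets BCL2 did not have 2 modes (gain in BIC of -1.5), and the B cell relation of the lower mode turned to 0.23. Of the other BCL2 probe sets, 1 went with the brightest (r = 0.73) and 2 against it (r = -0.18 and -0.26).

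**Figure D3:**
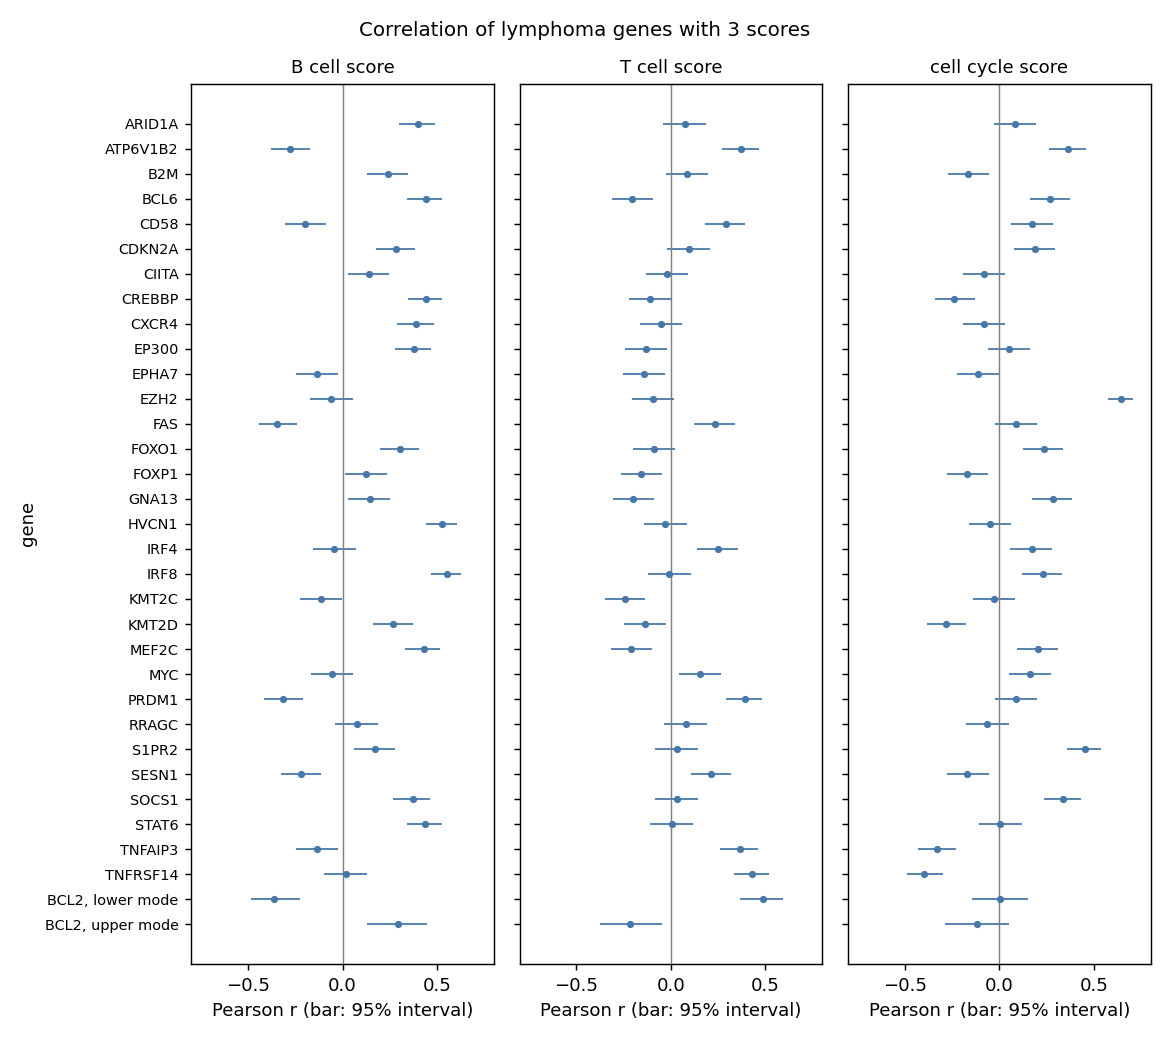
Pearson correlation r (horizontal axis, no unit) of each of 31 lymphoma genes (vertical axis) with the B cell, T cell and cell cycle scores over 302 biopsies, with 95% intervals as bars. BCL2 is drawn within its upper mode (130 biopsies) and its lower mode (the other biopsies). The value of EZH2 with the cell cycle is 0.64, and BCL2 changes sign between its modes for B and T cells.

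A linear model of each gene on the 6 main scores together asked which genes moved with a cell type when the others were held fixed. Slopes are log2 units per SD of a score with their standard error over 302 biopsies, and a gene was called at an adjusted limma p under 0.05 and a slope of at least 0.25 in size. Each list member was tested against scores made without it, and 9865 genes were tested. Of the follicular lymphoma genes HVCN1 was called with B cells (0.29 ± 0.04), BCL2 over both its modes with T cells (0.46 ± 0.12), EZH2 and S1PR2 with the cell cycle and PRDM1 with stroma (0.28 ± 0.07). IRF8, CREBBP, STAT6 and BCL6 were not called with B cells, nor TNFRSF14, PRDM1 and TNFAIP3 with T cells. The calls of BCL2 (0.30) and PRDM1 (-0.03) ended without the 26 biopsies, and both ended with the mean of probe sets. The call of BCL2 also ended with the T cell score alone in the model (0.16) and that of PRDM1 after adjusting for the array measures (0.18).

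For B cells, 1.49% of the 9865 genes were higher and 0.689% lower. Of the 15 tested genes of the B cell list, 9 were higher (9 adjusted over the list alone), with CD79B at 0.49 ± 0.04, VPREB3 at 0.49 ± 0.07, SPIB at 0.41 ± 0.04 and PAX5 at 0.31 ± 0.03. MS4A1 had a slope of 0.12 ± 0.03 and was below the minimum. Among naive and memory B genes 4 of 9 were higher (4 adjusted over the list alone), including TCL1A (0.51 ± 0.09), the BAFF receptor gene TNFRSF13C (0.39 ± 0.04) and FCER2, which encodes CD23 (0.39 ± 0.12). In the germinal centre list 2 of 10 were higher (2 adjusted over the list alone), SERPINA9 (0.34 ± 0.10) and ELL3 (0.30 ± 0.05). Of the MHC class II genes 2 of 12 were higher (2 adjusted over the list alone), HLA-DOB (0.43 ± 0.05) and HLA-DQB1 (0.29 ± 0.05). Outside the lists the 12 steepest included HLA-DRB4 (0.65 ± 0.26, adjusted p = 0.042), EML6 (0.55 ± 0.14), the tetraspanin gene CD37 (0.55 ± 0.05), TCL6 (0.47 ± 0.08), LY86, a partner of the RP105 receptor (0.45 ± 0.05), KLHL14 (0.41 ± 0.04), PTPRCAP (0.41 ± 0.04) and FCRL2 (0.41 ± 0.09). HLA-DRB4 had 2 modes, and within neither did its value go with the B cell score. There r was 0.07 in the lower mode (raw permutation p = 0.472) and 0.08 in the upper (p = 0.251). PRKAR2B, a regulatory subunit of protein kinase A (-0.42 ± 0.06), the RNA-binding protein gene IGF2BP2 (-0.39 ± 0.06) and ETV1 (-0.34 ± 0.07) were lower. So were the fat genes LPL (-0.28 ± 0.06) and ADH1B (-0.31 ± 0.11), 2 of 3 adipocyte genes (2 adjusted over the list alone). With quantile normalization 1.45% were higher and 0.314% lower, and with the mean of probe sets 1.1% and 0.162%, so most of the loss was among lower genes. Without the 26 biopsies of the lower stromal mode 1.44% were higher and 1.18% lower, and 4 of the 12 MHC class II genes were higher. The calls of ADH1B, ELL3, HLA-DQB1, HLA-DRB4, KLHL14, LPL and PAX5 ended with the mean of probe sets, and those of ADH1B, ETV1, HLA-DQB1, LPL and SERPINA9 with quantile normalization.

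For T cells, 3.54% of genes were higher and 0.253% lower. All 14 tested genes of the T cell list were higher (14 adjusted over the list alone), such as BCL11B (0.60 ± 0.04), LAT (0.59 ± 0.03), CD6 (0.56 ± 0.03) and CD3D (0.54 ± 0.03). Of 11 follicular helper genes 8 were higher (8 adjusted over the list alone), with TOX2 (0.84 ± 0.05), the costimulator ICOS (0.71 ± 0.05), MAF (0.57 ± 0.04) and the B cell attracting chemokine CXCL13 (0.43 ± 0.09). Regulatory genes were higher in 5 of 8 (5 adjusted over the list alone), with CTLA4 (0.66 ± 0.07) and TNFRSF4 (0.44 ± 0.04). Naive and central memory genes were higher in 5 of 9 (5 adjusted over the list alone), with MAL (0.67 ± 0.05) and LEF1 (0.64 ± 0.04). Dendritic cell chemokines moved with them too, CCL22 (0.71 ± 0.15) and CCL17 (0.54 ± 0.12), within a conventional dendritic list where 4 of 6 were higher (4 adjusted over the list alone). Of the neutrophil and blood monocyte genes 5 of 7 were lower (5 adjusted over the list alone), such as VCAN (-0.49 ± 0.09) and S100A8 (-0.45 ± 0.12). Outside the lists the 12 steepest included TIAM1, an activator of the RAC1 GTPase (0.71 ± 0.03), ICA1 (0.70 ± 0.05), PMCH (0.68 ± 0.10), DNASE1L3 (0.63 ± 0.08), the ganglioside synthase gene ST8SIA1 (0.58 ± 0.04) and TBC1D4 (0.57 ± 0.06). The apoptosis gene HRK (-0.45 ± 0.15, adjusted p = 0.022) and SOX5 (-0.43 ± 0.14) were lower. Without the 26 biopsies, 0 of 7 neutrophil and blood monocyte genes were lower and 2 of 6 conventional dendritic genes were higher, and the calls of HRK (-0.32), CXCL13 (0.16), VCAN (-0.23) and S100A8 (-0.27) ended. With the T cell score alone in the model, S100A8 had the opposite slope of 0.12, and the calls of CCL17 and SOX5 ended.

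For cytotoxic cells, 0.791% of genes were higher and 0.831% lower. Of the 14 tested genes of their list 13 were higher (13 adjusted over the list alone), with GZMH (0.90 ± 0.08), CCL5 (0.85 ± 0.06), GZMA (0.78 ± 0.05), NKG7 (0.77 ± 0.06) and CD8A (0.61 ± 0.06). IFNG, the gene of interferon gamma, was the steepest outside the lists (0.83 ± 0.08). Interferon gamma response genes were higher in 7 of 12 (7 adjusted over the list alone), with CXCL10 (0.65 ± 0.10), CXCL9 (0.64 ± 0.12) and IRF1 (0.31 ± 0.04). The type I interferon list had 5 of 14 higher (7 adjusted over the list alone), including IFIT3 (0.42 ± 0.08). The MHC class I list had 2 of 11 (2 adjusted over the list alone), the peptide transporter gene TAP1 (0.33 ± 0.05) and PSMB9 (0.26 ± 0.05). Also higher were the inhibitory receptor gene LAG3 (0.49 ± 0.06), the chemokine gene CCL4 (0.62 ± 0.07), XCL1 (0.74 ± 0.08) and CHI3L1 (0.66 ± 0.15). Other higher genes were the thrombin receptor gene F2R (0.61 ± 0.09), GPR171 (0.44 ± 0.07), the homing receptor gene CXCR6 (0.43 ± 0.05) and the gamma delta T cell receptor segment TRDV3 (0.43 ± 0.07). Fibroblastic reticular genes were lower in 4 of 7 (5 adjusted over the list alone), with CCL21 (-0.69 ± 0.18) and IL33 (-0.40 ± 0.11). So were all 3 adipocyte genes (3 adjusted over the list alone), with LPL at -0.48 ± 0.09. SYT17 (-0.66 ± 0.17) and ADIRF (-0.50 ± 0.12, adjusted p = 0.0055) were lower as well. This score shared most with the others, with a variance inflation of 4.18, and 1 of 100 fits to shuffled scores called as many genes, with 4.16%. With the mean of probe sets 0.76% of genes were higher and 0.314% lower, so nearly all of the loss was among lower genes. Without the 26 biopsies 0.699% were higher and 0.385% lower. There 1 of 7 fibroblastic reticular genes was lower and 1 of 11 MHC class I genes higher, and the calls of CCL21 (-0.47), IL33 (-0.32), ADIRF (-0.40) and PSMB9 (0.25) ended. With the cytotoxic score alone in the model those of CCL21, IL33, ADIRF, PSMB9, LPL and SYT17 ended too.

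For macrophages, 2.68% of genes were higher and 0.0608% lower. Their own list had 8 of 12 higher (8 adjusted over the list alone), with C1QB (1.01 ± 0.08), CD163 (0.96 ± 0.10) and FCER1G (0.61 ± 0.04), while MS4A7 had a slope of 0.03 ± 0.07. The 12 steepest outside the lists included MS4A4A (1.02 ± 0.08), the lectin genes CD209 (0.85 ± 0.12) and MRC1 (0.69 ± 0.08), SIGLEC1 (0.77 ± 0.10), the chemokine gene CCL18 (0.69 ± 0.12) and the elastase gene MMP12 (0.60 ± 0.12). Complement factor D, CFD (0.67 ± 0.08), and the plasma glutathione peroxidase GPX3 (0.66 ± 0.10) were higher as well. Among neutrophil and blood monocyte genes 4 of 7 were higher (5 adjusted over the list alone), such as S100A9 (0.81 ± 0.12). All 3 adipocyte genes were higher (3 adjusted over the list alone), such as FABP4 (0.95 ± 0.17). Fibroblastic reticular genes were higher in 5 of 7 (6 adjusted over the list alone), with CCL21 (0.84 ± 0.17) and CXCL12 (0.68 ± 0.13). Interferon gamma response genes were higher in 3 of 12 (3 adjusted over the list alone), with the tryptophan-degrading enzyme gene IDO1 (0.35 ± 0.07). The immune response 2 set had 2 of 5 higher (2 adjusted over the list alone), LGMN (0.56 ± 0.06) and C3AR1 (0.40 ± 0.04). The steepest lower genes were MTCL1 (-0.57 ± 0.16, adjusted p = 0.01), MIR3681HG (-0.34 ± 0.11) and SDK1 (-0.33 ± 0.08). The call of SDK1 ended without the 26 biopsies (-0.17), and those of MTCL1 (-0.47) and MIR3681HG (-0.33) without doubtful arrays.

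For stroma, 14.5% of genes were higher and 3.21% lower over all 302 biopsies, against 2.30% higher and 0.152% lower within the upper-mode biopsies. Of the genes called over all biopsies, 11.8% were called in the same direction within the upper mode. All 13 tested genes of the stromal list were higher in both (13 adjusted over the list alone), with COL3A1 (1.70 ± 0.05), FN1 (1.67 ± 0.08), COL1A1 (1.61 ± 0.07) and POSTN (1.33 ± 0.12) over the 302. The 12 steepest outside the lists, whose slopes within the upper-mode biopsies stand second here, included MXRA5 (1.53 ± 0.07, then 1.10), THBS2 (1.28 ± 0.07, then 0.92), SULF1 (1.35 ± 0.07, then 1.02) and COL5A2 (1.29 ± 0.05, then 0.86). Others of these 12 were C3 (1.53 ± 0.07, then 0.66), C1S (1.40 ± 0.08, then 0.43), the matrix protease inhibitor gene TIMP3 (1.43 ± 0.09, then 0.57) and SPARCL1 (1.49 ± 0.11, then 0.42). Of the fibroblastic reticular genes 7 of 7 were higher over the 302 (7 adjusted over the list alone), against 2 higher and 2 lower within the upper mode, where CCL21 turned from 0.83 ± 0.17 to -0.33. Endothelial genes were higher in 6 of 7 (6 adjusted over the list alone), with VWF (1.05 ± 0.10), and in 3 of 7 within the upper mode. Follicular dendritic genes were higher in 6 of 9 (6 adjusted over the list alone), with FDCSP (1.03 ± 0.12) and VCAM1 (0.95 ± 0.09), and in none within the upper mode, where 1 was lower. Immediate early genes were lower in 8 of 11 (9 adjusted over the list alone), with JUN (-0.61 ± 0.13) and DUSP1 (-0.48 ± 0.16). None of the 10 tested within the upper mode was called either way, where the slope of JUN was 0.05 and that of DUSP1 0.16. Light chain genes were lower in 4 of 5 (5 adjusted over the list alone), with IGLV1-44 (-0.66 ± 0.19), and in none of the 5 within the upper mode. HRK (-0.56 ± 0.19, then -0.39) was lower and called in both. RGS2 (-0.55 ± 0.09, then -0.09) and PCIF1 (-0.55 ± 0.07, then -0.12) were lower over the 302 and not called within the upper mode. Adjusting for the array measures called 6.65% of genes in place of 17.7%.

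For the cell cycle, 4.25% of genes were higher and 1.44% lower. All 17 tested genes of the list were higher (17 adjusted over the list alone), with RRM2 (0.85 ± 0.02), CCNB2 (0.84 ± 0.02) and CDK1 (0.83 ± 0.03). Germinal centre genes were higher in 7 of 10 (7 adjusted over the list alone), with GCSAM (0.42 ± 0.04), ELL3 (0.35 ± 0.04), RGS13 (0.34 ± 0.06) and S1PR2 (0.32 ± 0.04), and EZH2 had a slope of 0.42 ± 0.03. MYC targets were higher in 4 of 13 (4 adjusted over the list alone), with the nucleotide kinase gene NME1 (0.52 ± 0.03) and the lactate dehydrogenase gene LDHA (0.38 ± 0.02). Glycolysis genes were higher in 3 of 13 (3 adjusted over the list alone), with TPI1 (0.31 ± 0.03). The mitochondrial chaperone genes HSPE1 (0.34 ± 0.02) and HSPD1 (0.26 ± 0.02) were the 2 of 8 heat shock genes that were higher (2 adjusted over the list alone). Outside the lists the 12 steepest included CFAP251 (0.94 ± 0.10), the mitotic motor gene KIFC1 (0.88 ± 0.04), PBK (0.85 ± 0.03), the spindle gene ASPM (0.85 ± 0.04), HJURP, which loads the centromere histone (0.84 ± 0.02), and PCLAF (0.82 ± 0.02). CD23, from FCER2 (-0.60 ± 0.09), and the immediate early genes FOS (-0.49 ± 0.12) and DUSP1 (-0.41 ± 0.09) were lower, 4 of 11 in that list (4 adjusted over the list alone). So were ADIRF (-0.52 ± 0.06), the prostaglandin D2 receptor gene PTGDR (-0.48 ± 0.06) and CXCL2 (-0.46 ± 0.10, adjusted p = 7.5e-06). Adjusting for the array measures called 2.87% of genes (2.38% higher and 0.487% lower) in place of 5.69% and ended the calls of HSPE1, HSPD1, RGS13, S1PR2 and TPI1. Those of ELL3, HSPD1 and S1PR2 ended without the 26 biopsies, with 1 of 8 heat shock genes still higher. Fits to shuffled scores called at most 0.152% of genes for B cells, 1.96% for T cells, 0.0101% for macrophages, 0.294% for stroma and 0% for the cell cycle, in 100 shuffles each.

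**Figure D4:**
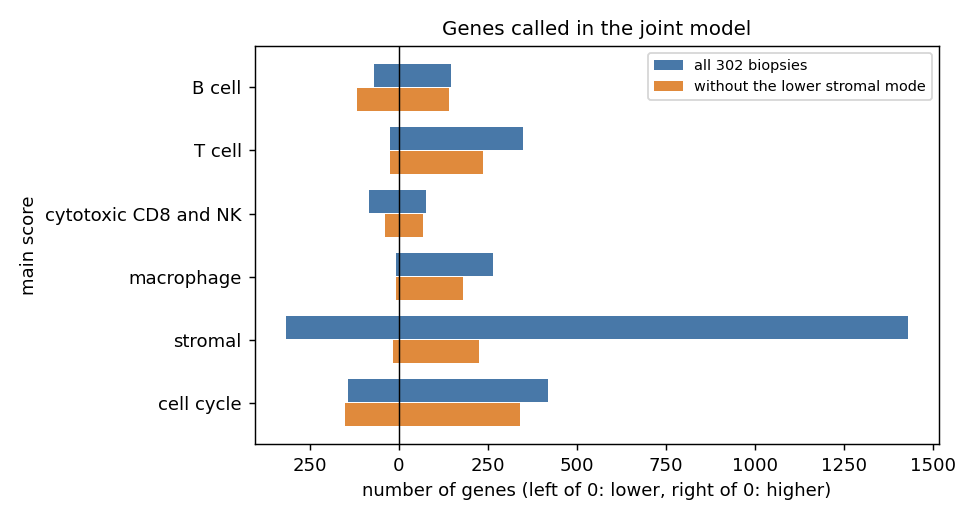
Number of genes of the 9865 tested (horizontal axis) that were higher (right of 0) or lower (left of 0) with each of the 6 main scores (vertical axis) in the joint model, over all 302 biopsies and without the 26 of the lower stromal mode. The stromal score had 14.5% of the tested genes higher over all biopsies and 2.30% without the 26.

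Some genes had 2 separate levels over the biopsies, and a gene of the MHC class II locus had the clearest. In its brightest probe set HLA-DQA1 lay at a log2 value of 5.53 or 13.49, with 63.6% of biopsies at the upper level. Another of its probe sets had 36.4% of biopsies at its upper level of 13.63. It went against the brightest (r = -0.33), while a further one went with the brightest (r = 0.95). Of all biopsies 14.9% were at the lower level of the brightest and of the opposed probe set. The 2 levels are therefore those of a probe set and not of all HLA-DQA1 transcripts. HLA-DRB4, a gene that only some haplotypes of the locus carry, lay at 6.77 or 13.44, with 62.9%. The call of HLA-DQA1 held with the mean of its probe sets, with a gain in BIC of 42.4 in place of 493.1. The next 10 genes by gain in BIC had 87.9% to 89.5% of biopsies at the upper level, among them SPARCL1 (6.40 and 12.23), the pericyte gene RGS5 (6.68 and 11.03), the endothelial adhesion receptor gene ADGRL4 (5.13 and 9.07), the coagulation inhibitor gene TFPI (5.71 and 10.04) and COL4A1, a basement membrane collagen (7.13 and 10.89). The others of these 10 were ARHGAP29, DCLK1, IL6ST, LIFR and PRSS23. Of these 10, IL6ST and LIFR did not gain over 10 on 1 skewed distribution. None of the 10 was called within the upper-mode biopsies or after adjusting for all technical measures, and of them only SPARCL1 was called after adjusting for the array measures. BCL2 was called as well, with 43.6% of biopsies at its upper level. Of the light chain genes, IGKC was not called and IGLC1 was (12.03 and 14.63, with 85.3% upper), though 1 skewed distribution fitted IGLC1 better (a gain of -25.28). Neither the difference of IGKC and IGLC1 nor that of IGKC and IGLV1-44 had 2 modes, with gains in BIC of -11.4 and 1.08. IGLV1-44 gained 27.2 with 54.1% of biopsies upper and was not called. In all, 3.37% of 9865 genes had a gain in BIC over 10, a smaller share of at least 10% and modes at least 3 component SDs apart. A skewed distribution with 1 mode passes these criteria in 10.8% of simulated genes, and 33.4% of the called genes also gained over 10 on 1 skewed distribution. Within the upper-mode biopsies 1.31% of genes had 2 modes, and 30.1% of the genes called over all biopsies were called there. After adjusting for all technical measures 0.395% of genes did, with 8.43% of the called genes among them.

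HLA-DQA1 and HLA-DRB4 varied most between biopsies when each gene was taken from its brightest probe set. With the mean of probe sets their SDs were 2.21 and 1.87, at ranks 5 and 10, and 9 of the first 20 genes stayed among the first 20. Of these 20 genes 14 stayed there without the 26 biopsies, 14 with all technical measures, 15 with the array measures and 15 with pseudocount 1. The SD of the log2 value had a median of 0.50 over 9865 genes, with a 5th percentile of 0.32 and a 95th of 1.07. Of these 615 genes were above 1 and 15 above 2. The largest SDs were those of HLA-DQA1 (3.94) and HLA-DRB4 (3.38), then CCDC85A (2.80), the adhesion gene PCDH9 (2.41) and SUGCT (2.30). Among the first 20 were also FABP4 (2.20), CCL21 (2.14), LUM (2.07), LIFR (2.06), SPARCL1 (2.04), C7 (2.001) and MGP (1.997). Lactoferrin, LTF (2.21), the chemokine gene CXCL5 (1.98), the immediate early gene FOS (2.07), the haemoglobin gene HBB (1.96), the immunoglobulin heavy chain locus IGH (2.03), BMP7 (2.03), BTNL9 (1.96) and RASSF6 (1.96) made up the rest. Of 37 lists with at least 3 tested genes, 33 varied together more closely than 95% of random lists of like size and level. The mean pairwise r was 0.87 for ribosomal protein genes, 0.80 for stromal, 0.73 for cell cycle, 0.635 for T cell and 0.248 for B cell genes, against a random median of 0.045 for the B cell list. The lists below that level were naive and memory B, plasmacytoid dendritic, epithelial and the follicular lymphoma genes, the last at the 65.22nd percentile.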

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

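The alternatives of control probe sets, of all technical measures together, of genes above the median level, of leaving out the 26 biopsies and of a skewed distribution were chosen only after the results were seen. Of 190 alternative values of the main pairs, 2 were weaker, 10 passed newly, 6 turned and the rest kept direction and side of the threshold, as did all 15 pairs with either other pseudocount, quantile normalization, block adjustment, genes above the median level and without doubtful arrays. Of 3713 for lists and lymphoma genes 89.1% kept both, 5.2% were weaker, 3.91% passed newly and 65 turned. Of 5860 for genes in the joint model 89.7% kept both, 571 were weaker, 1 passed newly and 30 turned. Of 78 for BCL2 in its modes 68 kept both, 6 were weaker, 1 passed newly and 3 turned. Of those for 9 pairs within the lower stromal mode 81 kept both, 17 were weaker, 8 passed newly and 1 turned, that of the cell cycle and fibroblastic reticular transcripts (-0.14 with the other main scores held fixed). Pairs of cell lists passing there were 2 with the other main scores held fixed, with pseudocount 64 or with the mean of probe sets, and 5 with genes above the median level or poly-A controls. Pairs of function lists passing there were 1 with quantile normalization, 3 with block adjustment, 2 with all technical measures, and 0 with the mean of probe sets, without doubtful arrays or with poly-A controls. Of 27 for lists with 2 modes 21 kept the call and 6 lost it, all 6 under the array measures alone or with the other technical measures. The precision of weak genes is limited by signal over background, which the pseudocount and filter alternatives probe. With the other main scores held fixed, r was -0.01 for B and T cells, -0.16 for T cells and macrophages, 0.15 for T cells and the cell cycle, -0.43 for cytotoxic cells and stroma, -0.12 for cytotoxic cells and the cell cycle, -0.03 for macrophages and regulatory T cells, 0.07 for B cells and follicular dendritic cells and -0.02 for macrophages and epithelium, and 39 function pairs passed. B cells and the cell cycle had r = 0.15 with median scores, 0.17 with the mean of probe sets, 0.15 adjusted for poly-A controls and 0.16 without the 26, and passed under each of these. Adjusted for array measures, r was -0.16 for T cells and stroma, -0.18 for cytotoxic cells and stroma and 0.17 for stroma and the cell cycle; with all technical measures these were -0.14, -0.18 and 0.21. Macrophages and the cell cycle had -0.13 adjusted for poly-A controls and -0.15 without the 26, where T cells and the cell cycle had -0.13. In the lower mode of BCL2, the mean of probe sets gave 0.23 with B cells and -0.32 with the cell cycle, and leaving out the 26 gave -0.28 with the cell cycle. Counts of genes follow as a percent of 9865. The joint model called 1.27% for B and 1.07% for cytotoxic cells with the mean of probe sets, 6.65% for stroma and 2.87% for the cell cycle adjusted for array measures, 4.99% and 2.61% with all technical measures, and 2.45% for stroma without the 26. With no filter it called 3.69% for B cells, 5.81% for T cells and 8.59% for the cell cycle, where more genes were tested. At the 75th percentile it called 1.15%, 1.45%, 0.487%, 0.720%, 7.24% and 2.58% for B cells, T cells, cytotoxic cells, macrophages, stroma and the cell cycle, where fewer genes were tested. With no filter 19730 genes were tested and at the 75th percentile 4933, while these percents are still of 9865. They therefore do not show whether the share of tested genes called rose or fell. A single score at a time gave 14% for B cells, 4.08% for cytotoxic cells and 13.1% for macrophages, and no minimum slope 34.4%, 19.7%, 3.29%, 8.47%, 56.9% and 61.4% in the same order. Without the 26, slopes on stroma were -0.33 for CCL21, 0.05 for JUN and 0.16 for DUSP1, and with 1 score at a time that of S100A8 on T cells was 0.12. Genes with 2 modes were 0.801% adjusted for array measures, 1.65% for blocks, 1.30% for poly-A controls and 0.395% for all technical measures. They were 1.31% without the 26, 43.4% with no filter, 1.87% at the 75th percentile, 0.811% at 4 SDs, 19.2% at a share of 5% and 1.13% over a skewed distribution too. The values with no filter and at the 75th percentile are of 9865 as well, though 19730 and 4933 genes were tested. They are not shares of the genes tested there and cannot be set against the main share. The median SD was 0.42 with all technical measures. Of the SDs of 20 named genes 31 values moved, 11 of 18 with the mean of probe sets, 7 of 20 with pseudocount 64, 6 of 20 without the 26, 5 of 20 with all technical measures and 2 of 19 with pseudocount 1. Where the number of genes or biopsies or the criterion itself did not change, the cause was not tested.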

Other observations

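The tests of the stromal score, of HLA-DQA1 and of BCL2 with naive and central memory T cells, and the genes singled out here outside the naming rule, were chosen only after the results were seen. IGHM, the constant segment of the IgM heavy chain, had 2 levels (11.23 and 14.63 on the log2 scale, 60.6% of biopsies upper), as did the germinal centre gene LMO2 (10.63 and 13.26), CCDC85A (6.09 and 11.24) and PCDH9 (7.42 and 11.56). Within the lower level of IGHM (39.4% of biopsies) its value went with the T cell score (r = 0.43, rho = 0.43, r without 2 biopsies 0.45, raw permutation p = 1e-05, the smallest the resamples can give), and within the upper level (60.6%) against it (r = -0.25, rho = -0.24, r without 2 biopsies -0.20, raw p = 0.00061 for r and 0.0015 for rho). PCDH9 did likewise, with r = 0.34 (rho = 0.29, r without 2 biopsies 0.28) in its lower level and r = -0.34 (rho = -0.39, r without 2 biopsies -0.36) in its upper level. These p-values were not adjusted, and 20 such genes were examined. Light chain genes were higher with the macrophage score in 3 of 5 (5 adjusted over the list alone) in the joint model, and in 5 of 5 within the upper-mode biopsies. Across the tested genes the closest pair of arrays had r = 0.986 and the next 0.972, against a median of 0.898, and in 0 pairs were most values identical. The first component of the tested genes held 26.6% of the variance, and 49 of 70 relations of scores and components with array measures passed.

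The stromal score had 2 modes, and no biological explanation was tested, since the design gives 1 group. The 26 biopsies lay in 6 of 8 blocks, with at most 6 in a block, so the lower mode was not made by whole blocks of title order. With so few in each block, adjusting for the blocks could hardly end the modes, and the gain in BIC of 103.6 left after it decides nothing. Batches smaller than a block were not tested and stay open. RNA of dispersed lymphoid cells in place of whole tissue stays open, as 0 of 15 lists of free immune cells had 2 modes and the follicular dendritic list, the 1 framework list outside the pattern, did not pass the rule for separate clusters (0 of 1), with modes 4.38 SDs apart and a gain of 108.74 over 1 normal but -26.18 over 1 skewed distribution. RNA quality and brightness cannot be told apart from it: adjusting for the array measures left a gain of 17.4 and all technical measures together -5.8, and these measures go with the cell lists themselves.

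BCL2 went with T cells in its lower mode and with B cells in its upper mode. With the other main scores held fixed only the first relation passed (0.45), not that of B cells in the lower mode (-0.08) or those of B cells (0.14) and T cells (-0.07) in the upper. A candidate explanation is BCL2 transcripts of T cells in lower-mode biopsies. With the naive and central memory T list r was 0.490 in the lower mode (permutation p = 1e-05, the smallest possible) and -0.011 in the upper (p = 0.906). This list goes with the T cell score (0.658). Only the 0.255 left in the lower mode with that score held fixed (permutation p = 0.00085) is therefore separate from the pattern. IGHM, an immunoglobulin heavy chain gene, changed sign in the same way, with r = 0.433 and -0.248 with the T cell score in its lower and upper mode. Such a change therefore does not by itself point to transcripts of T cells, and which cells made BCL2 was not measured. Dividing any gene with 2 modes stays open, as 3 of 20 other such genes (IGHM, PCDH9 and LMO2) had that change of sign, between the bounds set for and against it, though in the lower mode of LMO2 r = 0.223 fell to 0.081 without 2 biopsies and rho was 0.143 (p = 0.0936). The probe set stays open too, as another BCL2 probe set gave 0.218 (p = 0.00458) in the lower mode and -0.035 (p = 0.697) in the upper.

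HLA-DQA1 had 2 modes. Loss of MHC class II in part of the biopsies is argued against, as 0 of HLA-DRA, HLA-DPA1 and HLA-DPB1 had 2 modes in the brightest probe set of each. A dimmer HLA-DPB1 probe set did have 2 modes, with 10.22% of biopsies upper. Alleles that different probe sets read stay open. In the lower mode of both probe sets were 14.90% of biopsies, between the bounds set for and against this, where independent modes would give 23.16%. The probe sets had an r of -0.33 with each other. The brightest had 36.4% of biopsies in its lower mode, so part of these were in the upper mode of the other probe set. The bounds cannot decide the question, since biopsies whose alleles neither probe set reads would be in the lower mode of both. Probe sets of HLA-DQB1 differed as well. Its brightest did not have 2 modes (gain in BIC of -4.35), while another did (442.6).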
